A study of Mus musculus with 2 samples.

How the data were processed

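Single cells from hearts of male C57BL/6 mice were profiled with droplet 3' RNA sequencing (10x Genomics Chromium Single Cell 3' v3.1 chemistry, per the labels' protocols). There were 2 libraries, 1 from an untreated control heart sample and 1 from a heart sample of diabetic mice given streptozotocin (STZ), a toxin of the insulin-producing cells of the pancreas, at 150 mg/kg. The number of animals behind each library, the hour of collection and the days between injection and collection were not given in the sources used here.

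The deposited values were raw UMI counts per gene and cell barcode, made with Cell Ranger 3.1.0 per the file headers. CASAVA 1.8 and Seurat 2.3.4 are also named in the submitters' processing notes. The genome build and annotation behind the counts were not given in the sources used here. No cell annotation was used here, so cell classes were rebuilt from the counts. The lowest total in any barcode was 500 UMIs in both libraries. Coordinates come from GENCODE M21 (GRCm38), in which 30843 of the 30905 gene IDs were found. Gene symbols are those of the deposited tables, and 62 symbols were carried by several gene IDs.

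Cells were kept with at least 500 UMIs, at least 300 genes and at most 25% mitochondrial UMIs. This left out 1047 control and 2273 diabetic barcodes for their mitochondrial percentage, and 242 control and 823 diabetic barcodes had fewer than 300 genes. Doublets were scored with Scrublet as run in scanpy. Its own threshold marked 49 control cells (0.667%) and 8 diabetic cells (0.139%). The rate of 0.8% per 1000 barcodes assumed here gives 431 and 263. Whether the caller had worked was not tested. The highest scores in each library were therefore left out at 0.8% per 1000 barcodes, which took 431 control and 263 diabetic cells. The remaining 6911 control and 5475 diabetic cells had median depths of 5182 and 5508 UMIs.

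Counts were scaled per cell and log-transformed, 2000 variable genes were chosen per library, and 30 principal components with 15 neighbours gave 30 Leiden clusters at resolution 1. No integration between the libraries was applied. Each cluster was scored against markers of 21 classes fixed before the data were examined. A cluster took the name of the best class, as "X-like", with a score of at least 0.3 and a runner-up below 0.7 of it. It also needed at least 3 of that class's markers detected in 10% of its cells. It stayed unnamed where its 10 leading genes held more markers of another class, or where its depth was low and none of its markers led it. The markers were fixed beforehand, while these score thresholds were set after the clusters had been seen, so the shares of the unnamed clusters are given. Fibroblast-like cells were clustered again with 20 components at resolution 0.5, with all variable genes and, as an alternative added after the data were seen, without 2211 genes that differed 1.5-fold between the libraries. Sub-clusters are called by number.

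UMIs were summed per library and class, for the 5 classes with at least 100 cells in each library (20 under an alternative). They were scaled to CPM, each gene's part of the UMIs of nuclear-encoded genes in that class, and compared as the log2 of the diabetic over the control CPM. Sums and CPM carry exact Poisson intervals, ratios the exact conditional-binomial interval, and shares the Clopper-Pearson interval, all at 95%. These intervals cover counting error only. With 1 library per group no test across samples exists, and no p-values were computed. The share of cells with a Lox UMI was taken after thinning every cell to 1000 UMIs, as the mean over all possible thinnings, with shallower cells left out. Endothelial-like cells served as the background for that share.

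Before the data were examined, 46 gene lists were fixed, covering matrix, immune, metabolic, stress, clock, vascular and cell class genes. For each list the median log2 ratio was taken over members with at least 20 UMIs, with counts of members at least 1.5-fold higher or lower, and a member with 0 UMIs in 1 library was set at the bound that 3 counts give. Its percentile among 10000 random lists of the same size, each member drawn from the 100 genes nearest in mean expression, describes these 2 libraries and is no test. A list of cardiomyocyte stress genes was not used, because the cardiomyocyte-like class had fewer than 100 cells in each library.

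Named genes followed a rule fixed beforehand. They needed at least 50 UMIs over both libraries, at least 50 CPM in the higher library, and there a CPM at least 0.25 of that of the highest compared class. Mitochondrially encoded, ribosomal protein and haemoglobin genes and provisional gene models were left out. Genes were ranked by the interval bound nearest to no difference, and the 12 highest and 12 lowest were named in fibroblast-like cells, and 6 and 6 in each other class. The Lox family, Txnip, Pdk4, Angptl4 and up to 4 members of each list with at least 50 UMIs and the greatest absolute log2 ratio were also named. A few genes that the rule names are not used here. Genes with near-identical copies share reads, so values for haemoglobins, the Hspa1a and Hspa1b pair, and AY036118, which overlaps ribosomal RNA sequence, are uncertain.

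The ratio step was tested on simulated counts for the fibroblast-like comparison, over 12275 genes of which 100 were changed 3-fold and 100 were changed 1.5-fold. It recovered 100% of the 3-fold and 90% of the 1.5-fold changes, and 95.4% of the intervals held the true ratio. The counts were drawn from the Poisson model that the intervals assume. That coverage therefore checks the calculation and says nothing about variation between cells or libraries. The changed genes were drawn from well-expressed ones only. Of 40 lists of unchanged genes, 3 lay outside the middle 95% of their random lists. The clustering step separated 400 simulated cells of a strongly differing pair of types into 2 clusters, after a weaker simulated difference had not been separated.

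Alternatives changed the mitochondrial maximum, the UMI minimum, the doublet treatment, the resolution, the naming of cells, the scaling, the weighting of cells, the UMI minimum of list members, the depth of thinning and the rule for named genes. A further 10 were added after the data were seen. The analysis used Python 3.11.15, scanpy 1.11.5, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, leidenalg 0.10.2, igraph 0.11.9 and matplotlib 3.10.9.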

Results

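Cells of the mouse heart were compared between 1 library from untreated control mice and 1 library from mice made diabetic with STZ (150 mg/kg). The control library held 8631 barcodes with 53021783 UMIs in all and a median of 4435 per barcode. The diabetic library held 8834 barcodes with 44901775 UMIs and a median of 3785.5. Median mitochondrial percentages were 9.36% in control and 17.9% in diabetic barcodes. Each difference below is between these 2 libraries and has no replicate check, and each interval covers counting error only. A list median within the middle 95% of its matched random lists is given as a value with no direction.

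The series text asks how endothelial cells, fibroblasts, macrophages and other cell types of the heart differ in diabetes. Fibroblast-like cells, the producers of heart matrix, were 23.0% of retained diabetic cells (Clopper-Pearson 95% interval 21.9 to 24.1) and 13.8% of control cells (13 to 14.6), a ratio of 1.67 (1.53 to 1.81). Macrophage-like cells, the main resident immune cells, were 3.96% of diabetic cells (3.46 to 4.51) and 6.44% of control cells (5.87 to 7.04), a ratio of 0.616 (0.521 to 0.726). Endothelial-like cells, which line the vessels, were 45.8% and 44.1%, a ratio of 1.04 (0.984 to 1.09). Smooth muscle-like cells were 2.72% of diabetic and 1.48% of control cells, a ratio of 1.84, and pericyte-like cells, which wrap capillaries, were 3.12% and 4.30%. Endocardial-like cells were 1.06% and 1.17%, and Schwann-like cells 0.712% and 0.666%. Monocyte-like cells were 0.457% and 0.289%, B cell-like cells 0.274% and 0.391%, lymphatic endothelial-like cells 0.402% and 0.622%, and mesothelial-like cells 0.146% and 0.101%. For each of these last 6 classes the interval of the ratio included 1, and for 5 of the 6 the ratio crossed 1 under at least 1 alternative, so no direction is read.

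These shares depended on which cells were kept. The filters were 500 UMIs, 300 genes and 25% mitochondrial UMIs, and the last of these removed 25.7% of diabetic and 12.1% of control barcodes. With at most 10% mitochondrial UMIs the fibroblast-like ratio was 2.45, the endothelial-like ratio 0.378 and the macrophage-like ratio turned to 1.21. With no mitochondrial maximum the fibroblast-like ratio turned to 0.835, or was 1.3 when clusters were also named without the rule on leading genes, which had left a fibroblast cluster of 1812 cells unnamed. The smooth muscle-like share of cells, diabetic over control, was 6.00 with at most 10% mitochondrial UMIs, from 11 control and 35 diabetic cells, 1.15 with classes named per cell and 1.26 without cluster 24, which is described with these cells. Unnamed clusters held 25.8% of control and 16.4% of diabetic cells. Of all cells, 17.4% of control and 5.97% of diabetic cells lay in unnamed clusters of low depth. A further 6.71% and 8.68% lay in clusters led by another class's markers, and 1.75% and 1.79% in clusters that scored alike for 2 classes. Clusters 3 and 8 held most control fibroblast-like cells and clusters 3 and 9 most diabetic ones. Immune and stress genes such as Serpina3n, Il6, Ptgs2 and Mt2 were among the leading genes of cluster 9. Most diabetic endothelial-like cells lay in cluster 0 and most control ones in clusters 1 and 5, and interferon-induced genes such as Cxcl9, Iigp1 and Rsad2 led cluster 5.

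**Figure D1:**
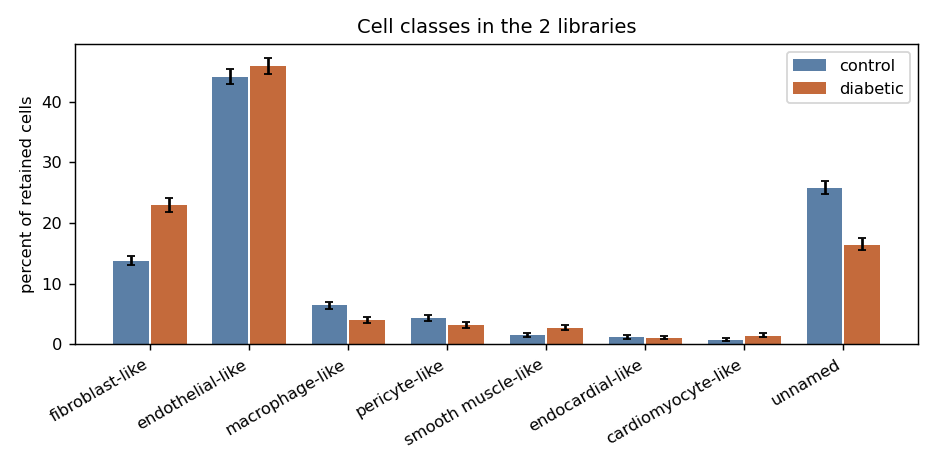
Share of retained cells in each class, in percent, for the control and the diabetic library, with Clopper-Pearson 95% intervals as bars. Fibroblast-like cells were 13.8% of control and 23.0% of diabetic cells, and macrophage-like cells 6.44% and 3.96%.

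The second question of the series is the role of Lox, lysyl oxidase, the secreted enzyme that starts the cross-linking of collagen and elastin, in fibroblast subtypes. In fibroblast-like cells Lox was 3.91-fold higher in the diabetic library (3.47 to 4.41), with 137 CPM (130 to 145, 1367 UMIs) against 35.1 CPM in control (31.5 to 39.0, 343 UMIs). Transcripts of most fibrillar collagens, which Lox acts on, were lower in the diabetic library, and so were most interferon-stimulated genes. Many genes of fatty acid use, many chemokines and the complement gene C4b were higher. The log2 ratio of Lox was 1.97 (1.79 to 2.14). It was 0.85 with no mitochondrial maximum, 1.31 with Scrublet's own threshold and 1.34 with no doublets left out, settings in which the rule on leading genes left fibroblast clusters unnamed. The largest of these clusters, of 1812, 969 and 1369 cells, had Ifi205, a marker fixed for dendritic cells, among their leading genes and no fibroblast marker. Ifi205 itself had 457 CPM in control and 583 CPM in diabetic fibroblast-like cells. Lox lies on chromosome 18 from 52516067 to 52529867 on the minus strand (GRCm38, GENCODE M21), gene ID ENSMUSG00000024529.

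After thinning to 1000 UMIs per cell, 10.9% of diabetic fibroblast-like cells held a Lox UMI (9.24 to 12.8) against 3.03% of control ones (2.03 to 4.34). This left out 11 diabetic and 19 control cells. Unthinned shares were 38.7% and 21.1%, at median depths of 8380 and 10928 UMIs. The background in endothelial-like cells was 0.156% of diabetic and 0.148% of control cells after thinning, and 0.678% and 0.492% before it, at median depths of 4648 and 5173 UMIs. In smooth muscle-like cells Lox had 44 UMIs in the diabetic and 68 in the control library, a log2 ratio of -1.09 (Lox was looked up there after the data had been seen).

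Lox was concentrated in fibroblast sub-cluster 5, which it helped to define, at 375 CPM (347 to 404). That sub-cluster held 680 of the 1367 diabetic Lox UMIs, or 49.7%. The other diabetic fibroblast-like cells had 84.3 CPM (78.1 to 90.8, 687 UMIs), still 2.40-fold above control (2.11 to 2.74). When sub-clusters were drawn without the 2211 genes that differed 1.5-fold, the matching one held 21% of diabetic (18.8 to 23.3, 264 cells) and 0.630% of control fibroblast-like cells (0.231 to 1.37, 6 cells). It shared 231 cells with sub-cluster 5, which had 252. Lox was among the genes left out of this second clustering and still stood at 342 CPM (316 to 370) in that sub-cluster. No control cell lay in sub-cluster 5, but 9 of its 10 leading genes differed 1.5-fold between the libraries, so its composition is not compared. For the matching sub-cluster 9 of 10 differed as well, so its shares above are a description only. A sub-cluster made mostly of 1 library can reflect that library rather than a cell type. In the 4 sub-clusters of this second clustering with at least 100 cells per library, the log2 ratio of Lox ran from 0.43 (-0.24 to 1.11), in the one led by Cd248, Sema3c and Pi16, to 1.62 (1.29 to 1.95). This within-sub-cluster comparison was chosen after the data had been seen.

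**Figure D2:**
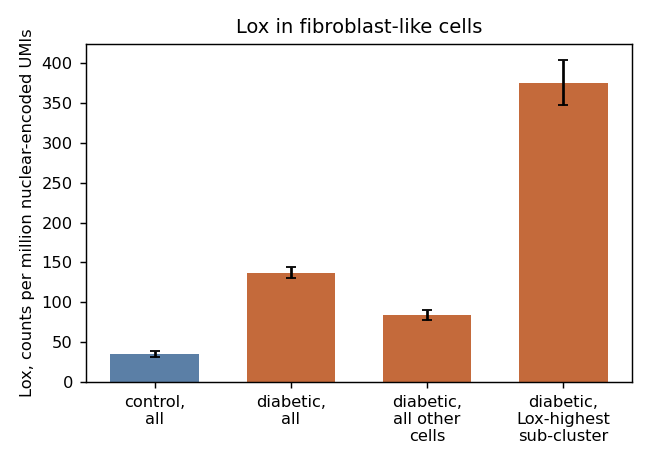
Lox level in fibroblast-like cells in CPM, for control cells, diabetic cells, diabetic cells outside the Lox-highest sub-cluster, and that sub-cluster, with exact Poisson 95% intervals as bars. The level was 35.1 in control cells, 137 in diabetic cells, 84.3 in diabetic cells outside the sub-cluster and 375 within it.

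Among the Lox family, Loxl4 had a log2 ratio of 1.53 (16 and 47 UMIs in control and diabetic), Loxl1 0.41, Loxl3 -0.23 and Loxl2 -0.41, and the family's median of 0.41 was at percentile 99.4 of matched random lists. Fibrillar collagens had a median of -0.87, at percentile 0, with 5 of 7 members at least 1.5-fold lower and 1 higher, the fold behind all such counts below. Col3a1 had -0.96, Col5a2 -0.94, Col1a2 -0.87 and Col5a3 0.74. Col1a1, chosen after its values were seen, had -0.71 (7235 and 11561 UMIs in diabetic and control). The median gene of fibroblast-like cells lay at -0.16, so counted from it each log2 ratio here is 0.16 higher. On that scale Lox had 2.12, 4 of the 7 fibrillar collagens were at least 1.5-fold lower and their median was -0.71. Within the same 4 sub-clusters the ratio of Col3a1 ran from -1.35 to -0.31 and the median of the fibrillar collagens from -1.06 to -0.31. The fibrillar collagens at least 1.5-fold lower numbered 0, 0, 6 and 2 in these 4 sub-clusters.

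The medians of 6 other matrix lists were below 0 as well. Matrifibrocyte genes, which mark the fibroblasts of mature scars, had a median of -1.08 with 7 of 9 lower. Among them Thbs4, a thrombospondin, had -2.69, Ddah1 -2.54 and Meox1 -1.07. Cluster 14, with 103 control and 82 diabetic cells, scored highest for fibroblasts but stayed unnamed, with the endocardial marker Cytl1 among its leading genes. Comp and Fmod of this list also led it, so these values leave out cells that express such genes. Chad, another member, had 54 control and 0 diabetic UMIs. At resolution 0.5 Chad had 403 and 240, a ratio of 0.613, and with no mitochondrial maximum its ratio was 1.12. Matricellular proteins had a median of -0.41, with 6 of 15 lower and 2 higher, among them Spp1 (osteopontin) at -2.46, Postn (periostin), a marker of activated fibroblasts, at -1.57, and Thbs2 at 1.53. Basement membrane genes had a median of -0.36 with 4 of 14 lower (Sparc -1.28, Col4a1 -0.76), and other interstitial collagens -0.44 with 2 of 8 lower (Col8a1 -1.33, Col16a1 -1.06). Proteoglycans had -0.38 with 2 of 9 lower (Fmod -0.80, which turned positive with no mitochondrial maximum and with no doublets left out, and Podn -0.79) and collagen-processing enzymes -0.36 with 1 of 13 lower, P4ha1, a prolyl hydroxylase, at -0.80. Each of these medians was below percentile 1 of matched random lists. Elastic fibre genes had a median of 0.05, with 3 of 13 higher, including Mfap2 at 1.24 and Fbln5 at 0.75. Proteases and their inhibitors had 0.03, with 5 of 14 higher, among them Mmp11 at 1.71, Adamts4 at 1.12 and Mmp14 at 0.80. TGF-beta genes had 0.19 with 1 of 15 beyond 1.5-fold, Ltbp2 at -1.98, and that median turned to -0.02 with no mitochondrial maximum. Myofibroblast contractile genes had 0.27 (Tpm2 0.94), which turned to -0.08 as a mean over cells, and among them Actn1 had -0.54, which turned to 0.24 with no mitochondrial maximum. Wnt antagonists had 0.26 (Sfrp1 0.52). Resident fibroblast genes (-0.10) and Pi16 adventitial genes (-0.10) changed sign between scalings.

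Chemokines and cytokines had a median of 0.61 in fibroblast-like cells, at percentile 100, with 9 of 17 members higher and 3 lower. Ccl11 (eotaxin) was 5.48-fold higher (5.08 to 5.90), Ccl7, which draws monocytes, 5.01-fold (4.71 to 5.32) and Ccl8 had a log2 ratio of 2.09, while Cxcl9, an interferon-induced chemokine, had -1.79. Cxcl5, which draws neutrophils, was 5.71-fold higher (4.66 to 7.05). Serpina3n, a protease inhibitor of the acute phase, was 5.59-fold higher (5.10 to 6.14) and C4b 5.36-fold (4.85 to 5.92). The complement list as a whole moved both ways, with C3 at 1.11, C7 at -1.68 and C1qa at -1.12, and its median of -0.05 changed sign between scalings. Interferon-stimulated genes had a median of -1.18, at percentile 0, with 15 of 18 lower, or 14 when counted from the median gene. Ifit3 stood at 0.212 of its control level (0.191 to 0.235), Isg15 at 0.241 (0.215 to 0.269), Irf7 at 0.322 (0.288 to 0.360) and Oasl2 at 0.336 (0.306 to 0.369), and Gbp3, also interferon-induced, at 0.271 (0.236 to 0.310). MHC class I genes had -0.35 (Tap1 -0.98) and MHC class II genes -0.63. Immediate early genes had 0.43 (Zfp36 1.03, Nr4a1 0.69) and heat shock genes 0.07 (Hspb1 0.62).

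Genes of PPAR signalling and fatty acid use had a median of 0.62, at percentile 100, with 9 of 17 higher, or 10 when counted from the median gene, and none lower. Within the 4 sub-clusters that median was 0.16 to 0.36. A sub-cluster of 81 cells led by the endothelial genes Fabp4, Cd36, Gpihbp1 and Flt1 stayed in the fibroblast-like class. Without it, an alternative added after the data were seen, the median was 0.38 with 7 of 17 higher, Fabp4 had 0.23 and Cd36 -0.23. When drawn without the differing genes, the sub-cluster led by the same 4 genes held 26 control and 38 diabetic cells. Angptl4, an inhibitor of lipoprotein lipase, was 9.90-fold higher (8.31 to 11.9), and Pdk4, which limits glucose oxidation, had a log2 ratio of 1.65. Plin2, a lipid droplet protein, had 1.18. Glucose-responsive targets had 0.53 (Arrdc4 0.75, Txnip 0.53) and glycolysis genes -0.33, with 3 of 14 lower, Slc2a1, the basal glucose transporter, at -1.09. Insulin and FoxO genes had 0.15 (Igfbp3 1.37, Insr 0.65), turning to -0.11 with no mitochondrial maximum. Antioxidant genes had 0.30, with 4 of 15 higher (Hmox1 1.08, Nqo1 0.79). Ribosomal protein genes had 0.33, with 13 of 93 higher. Nr1d1, a repressor of the circadian clock, was 5.02-fold higher (4.48 to 5.64), and Npas2 had 1.73 and Per2 -1.14 within a clock list median of 0.15. Glucocorticoid targets (-0.02, with Mt2 at 1.65 and Tsc22d3 at -0.90), hypoxia targets (-0.03), ER stress (-0.14), mitochondrially encoded (-0.03) and respiratory chain genes (-0.05) changed sign between scalings. Cell cycle genes had 0.04 and haemoglobins 0.29. Heart muscle transcripts, which are foreign to fibroblasts, had -1.26 and were 67.3 CPM of diabetic and 161 CPM of control fibroblast-like RNA, and median mitochondrial percentages were 5.39% and 5.75%.

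The other named genes of fibroblast-like cells had the following ratios. Tmem176a was 5.83-fold higher (5.16 to 6.60) and Tmem176b, its neighbour in the same family, 4.62-fold (4.23 to 5.06). Galnt15, a glycosyltransferase, was 5.39-fold higher (4.67 to 6.23) and Cnmd (chondromodulin) 5.40-fold (4.52 to 6.48), though Cnmd reversed with no mitochondrial maximum. AY036118 was 7.95-fold higher (7.12 to 8.91), with the uncertainty of its ribosomal RNA overlap. Angptl7 stood at 0.112 of its control level (0.0961 to 0.129), Col4a3, a basement membrane collagen, at 0.221 (0.188 to 0.258) and Cst6, a protease inhibitor, at 0.263 (0.219 to 0.313). Angptl7 was among the leading genes of unnamed cluster 14, whose cells its ratio leaves out. Ccnd1 (cyclin D1) stood at 0.338 (0.316 to 0.361), Postn at 0.336 (0.315 to 0.358), Thbs4 at 0.155 (0.126 to 0.188) and Ltbp2, a matrix protein that resembles TGF-beta binding proteins, at 0.253 (0.208 to 0.305). Within the 4 sub-clusters the log2 ratio of Angptl4 ran from 2.05 to 3.62, of Nr1d1 from 1.98 to 2.87, of Isg15 from -2.20 to -1.93 and of Ccl11 from 1.93 to 2.70, whereas Postn ran from -2.08 to 0.20. C4b ran from 0.27 (-0.28 to 0.81) to 2.53 and Pdk4 from 0.61 (-0.03 to 1.25) to 2.07, each with an interval that included 0 at its lowest.

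In endothelial-like cells, the next comparison the series text implies, the diabetic library was higher in many clock genes, in most genes of fatty acid use and in Cyp1a1, and lower in most interferon-stimulated genes. Cyp1a1, a classic target of the aryl hydrocarbon receptor, was 18.9-fold higher (16.7 to 21.4), with 289 against 15.3 CPM. Nr1d1 was 18.6-fold higher (15.2 to 23.0) and Dbp, a clock output factor, 12.2-fold (10.8 to 13.7). Interferon-stimulated genes had a median of -1.15, at percentile 0, with 17 of 18 lower. The median mitochondrial percentage was 15.4% in diabetic and 8.01% in control endothelial-like cells, and mitochondrially encoded genes had a median of 0.94. Haemoglobin RNA was 4272 CPM against 712 CPM, with a list median of 2.58, while fibroblast-like cells had 19.3 CPM in the diabetic and 15.8 CPM in the control library. Where it came from was not tested. TMM scaling added 0.19 to each log2 ratio of these cells and scaling over all genes took 0.12 away.

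The clock list had a median of 1.28, at percentile 100, with 7 of 13 higher, Bhlhe41 at 3.86 and Hlf at 1.99. The hours at which the hearts were collected, on which clock transcripts depend, were not given in the sources used here. Fatty acid use had 0.81 with 12 of 17 higher, including Pdk4 at 2.66, Cd36, a fatty acid carrier, at 1.46 and Angptl4, 5.52-fold higher (5.09 to 5.98). Capillary and lipid-handling genes had 0.36 (Fabp4 0.94, Car4 0.89, Aqp1 -1.17). Angiogenic genes had -0.62 with 5 of 10 lower, Esm1 at -1.89 and Angpt2 at -1.31 being tip cell and vessel-destabilising genes, although Plvap had 1.09. Arterial genes had 0.17 (Gja4 1.03, Gja5 -0.79), and basement membrane genes -0.39, with Col15a1 at -1.95. Col15a1 would be named in this class only without the minimum against the highest class, so RNA from other cells is not excluded for it. TGF-beta genes had 0.39 (Tgfb2 2.17, Tgfbr2 0.68), heat shock genes 0.44, immediate early genes 0.40 (Nr4a1 1.08) and antioxidant genes 0.34 (Nqo1 2.59, Hmox1 1.15). Glucose-responsive targets had 0.40 (Txnip 0.71), glucocorticoid targets 0.13 (Fkbp5 1.13, Tsc22d3 -1.01) and MHC class I genes -0.28 (Tap1 -0.90). Heart muscle transcripts had -0.41 and cell cycle genes -0.35 (Top2a -0.96), and both turned positive with at most 10% mitochondrial UMIs. Chemokines had -0.52 (Il6 2.02, Ccl4 -1.23), a median that also turned positive with that maximum, at resolution 0.5, with classes named per cell and with 1 UMI added.

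Pth1r, the parathyroid hormone receptor, was 10.2-fold higher (8.95 to 11.6) and Spock2, a matrix proteoglycan, 6.12-fold (5.12 to 7.36). Fam71a stood at 0.144 of its control level (0.115 to 0.180), Slco3a1, an organic anion transporter, at 0.296 (0.255 to 0.342), Isg15 at 0.273 (0.260 to 0.286), Oasl2 at 0.295 (0.270 to 0.321), Ifit3 at 0.323 (0.302 to 0.344) and Ifit1 at 0.336 (0.318 to 0.354). The medians of MHC class II (-0.03), glycolysis (between -0.12 and 0.19), insulin and FoxO (-0.15), hypoxia (-0.10), ER stress (-0.12), respiratory chain (0.11), ribosomal protein (-0.07), venous (-0.09) and flow genes (-0.04) changed sign between scalings. Within these lists Lrg1 had 3.18, Igfbp3 -1.19 and P4ha1 -1.23.

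Macrophage-like cells of the diabetic library were lower in most interferon-stimulated genes and higher in Ccr2, the receptor of recruited monocytes. Ccr2 was 4.14-fold higher (3.56 to 4.83) and Ccl8 4.02-fold (3.70 to 4.37), and Spp1 stood at 0.140 of its control level (0.0828 to 0.222). Interferon-stimulated genes had a median of -0.94 with 16 of 18 lower, Irf7 at 0.215 of control (0.179 to 0.257) and Isg15 at 0.265 (0.218 to 0.321). Cell cycle genes had -0.76 with 7 of 10 lower, Top2a at -1.50 and Mki67 at -1.25. Cluster 16, which scored highest for macrophages and had Mki67 and Top2a among its leading genes, stayed unnamed because it scored alike for mast cells. Counted as macrophage-like, an alternative added after the data were seen, it left the cell cycle median at -0.34 with 4 of 10 lower, Top2a at -1.04 and Mki67 at -0.99. The medians of immediate early, glycolysis and MHC class II genes, given below, then took the other sign. Median mitochondrial percentages were 6.58% and 7.30%, and heart muscle RNA was 167 CPM in diabetic and 463 CPM in control cells.

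The monocyte-derived list moved both ways, with a median of 0.06. S100a4 had 1.36 and Plac8 -1.70, which turned to 2.58 with classes named per cell. Ly6c2 had 58 control and 0 diabetic UMIs, but 1 and 0 with classes named per cell. The medians of resident macrophage genes (-0.01, with Timd4 at -0.82 and Vsig4 at 0.78), insulin and FoxO genes (-0.09) and glucocorticoid targets (-0.09) changed sign between scalings. Lipid-associated genes had 0.35 (Lgals3 1.03, Ctsd 0.79), turning to -0.01 when cells were named from markers without clusters. Fatty acid use had 0.34 (Angptl4 3.89, Cd36 1.59), chemokines 0.37, antioxidant genes 0.29 (Gpx3 2.73), immediate early genes 0.25, ribosomal protein genes 0.18, glucose-responsive targets 0.49 and hypoxia targets 0.19, which turned to -0.07 as a mean over cells. Gpx3 would be named in this class only without the minimum against the highest class, so RNA from other cells is not excluded for it. MHC class I genes had -0.58 (Tap1 -1.03), ER stress genes -0.46 (Ddit3 -0.74), basement membrane genes -0.27, glycolysis genes -0.10 (Slc2a1 -3.61) and mitochondrially encoded genes -0.14. MHC class II (0.10), complement (0.08, with Cfb at -1.35 and C2 at -1.34), respiratory chain (0.03), clock (0.00) and heat shock genes (0.00, with Hspb1 at 1.33) stood near 0. Ccdc152 was 5.82-fold higher (4.61 to 7.39), Lyz1, a lysozyme that shares reads with Lyz2, 4.41-fold (3.77 to 5.17), Clec10a, a lectin, 3.44-fold (3.02 to 3.92) and AY036118 9.93-fold (8.31 to 11.9). Ms4a4c stood at 0.226 (0.173 to 0.292), Slfn1 at 0.246 (0.170 to 0.346) and Lpcat2 at 0.263 (0.197 to 0.346).

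Pericyte-like cells of the diabetic library showed higher levels of many clock and lipid genes and lower levels of most interferon-stimulated genes. Nr1d1 was 20.6-fold higher (10.8 to 44.3), Angptl4 16.7-fold (8.90 to 34.6), Dbp 6.79-fold (4.91 to 9.55), Fabp5, a fatty acid-binding protein, 3.20-fold (2.94 to 3.48) and Plin2 3.04-fold (2.55 to 3.63). Fatty acid use had a median of 1.11 with 10 of 14 higher (Cd36 2.20), the clock list 0.78 and interferon-stimulated genes -1.26 with 13 of 18 lower. Cd36, with Cd300lg and Aqp1, would be named here only without the minimum against the highest class. RNA from other cells is therefore not excluded for Cd36, and the part of endothelial RNA in these cells was not tested. Ifit1 stood at 0.147 of control (0.0620 to 0.30), Ifit3 at 0.209 (0.119 to 0.345), Usp18 at 0.150 (0.0472 to 0.368), Eif2ak2 at 0.255 (0.106 to 0.534), Alkal2 at 0.266 (0.117 to 0.535) and Cxcl10, with 3 diabetic UMIs, at 0.104 (0.0208 to 0.318). Nppa, an atrial muscle hormone, was 9.18-fold higher (4.85 to 18.9) but turned to a log2 ratio of -0.26 with at most 10% mitochondrial UMIs, from 149 control and 53 diabetic cells, and heart muscle transcripts, foreign to pericytes, had 0.70. That median was 0.11 as a mean over cells and turned to -0.037 at resolution 0.5. Median mitochondrial percentages were 11.9% in diabetic and 9.91% in control cells. Contractile genes had -0.26 (Acta2 -0.82, or 0.28 with no doublets left out), basement membrane genes -0.24 (Col15a1 -2.19), antioxidant genes 0.53 (Gpx3 2.18), glucose-responsive targets 0.82 (Txnip 1.29), ribosomal protein genes 0.29 and mitochondrially encoded genes 0.29. Insulin and FoxO genes had 0.20, glucocorticoid targets 0.18, respiratory chain genes 0.17, TGF-beta genes 0.12, MHC class I genes 0.12, cell cycle genes 0.06, immediate early genes 0.03 (a median that changed sign between scalings), heat shock genes -0.08, glycolysis genes -0.08, hypoxia targets -0.10 and ER stress genes -0.28. As a mean over cells the MHC class I (-0.07), heat shock (0.11) and hypoxia medians (0.47) took the other sign.

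Smooth muscle-like cells of the diabetic library were lower in most interferon-stimulated genes and higher in the clock gene Nr1d1 and in many antioxidant and ribosomal protein genes. They fell into clusters 13 and 24, of which cluster 24 was mostly of the diabetic library and can reflect that library rather than a cell type. Of the 6 genes named as higher, 4 are given here and came with that cluster, and the others are not used here. Mfap4, a microfibril protein, had 278 diabetic and 0 control UMIs, and Osr1 76 and 0. Against a floor of 3 control UMIs these stood 67.4-fold and 18.4-fold higher, and the lower bounds of their exact intervals were 54.4 and 14.6. Sost, with 3 control UMIs, was 60.1-fold higher (20.3 to 293) and Fmo2 47.0-fold (23.7 to 109). These values depended on which cells were kept, and the 16 control smooth muscle-like cells left out as doublets held 96 UMIs of Mfap4, 41 of Osr1, 152 of Sost and 487 of Fmo2, a look taken after the data were seen. Those 16 cells had a median depth of 14284 UMIs against 8656 in the kept control cells, so true doublets among them are not excluded. With no doublets left out Mfap4 was 2.82-fold higher (2.24 to 3.58), Osr1 1.57-fold (1.06 to 2.35) and Sost 1.355-fold (1.10 to 1.67), and Fmo2 turned to 0.908 of its control level (0.802 to 1.03). In the same order the folds were 4.50, 2.56, 3.06 and 1.68 with at least 1000 UMIs, and 5.40, 2.89, 3.23 and 2.54 with no mitochondrial maximum. Without cluster 24, an alternative added after the data were seen, the genes named as higher included Nr1d1, Dbp, AY036118, Tcap and Ech1, with Dbp 11.5-fold higher (7.15 to 19.4). Tcap was also among the leading genes of the cardiomyocyte-like cluster. That class was not a compared class, so the minimum against the highest compared class could not screen out its RNA. Edn1 (endothelin), with 2 diabetic UMIs, stood at 0.0242 of control (0.00287 to 0.0914), Isg15 at 0.143 (0.0911 to 0.218), Irgm1 at 0.185 (0.0925 to 0.346), Neat1, a nuclear RNA, at 0.292 (0.264 to 0.322), Kitl at 0.343 (0.285 to 0.412) and Rrad at 0.352 (0.305 to 0.404). Interferon-stimulated genes had a median of -1.29 (10 of 14 lower) and fatty acid use 0.71 (Ech1 1.31). The clock list had 0.44 (Nr1d1 6.16, interval 3.64 to 11.5), antioxidant genes 0.76 and ribosomal protein genes 0.59 with 44 of 86 higher. Median mitochondrial percentages were 13.5% in diabetic and 14.2% in control cells. Contractile genes had 0.33, TGF-beta genes 0.24, hypoxia targets 0.49, glucose-responsive targets 0.86, immediate early genes -0.41, MHC class I genes -0.11 (0.36 as a mean over cells), glycolysis genes -0.12, glucocorticoid targets -0.08 (Mt2 2.90), basement membrane genes -0.08, mitochondrially encoded genes -0.17, heat shock genes 0.06, respiratory chain genes 0.08, cell cycle genes 0.09 and heart muscle transcripts -0.73. The last list moved both ways, with 2 of 8 higher and 4 lower and a median of -0.17 as a mean over cells, and its summed level was 1383 CPM in diabetic and 1349 CPM in control cells. Without cluster 24 the TGF-beta, hypoxia and mitochondrially encoded medians took the other sign. Insulin and FoxO (-0.03) and ER stress genes (-0.06) changed sign between scalings.

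**Figure D3:**
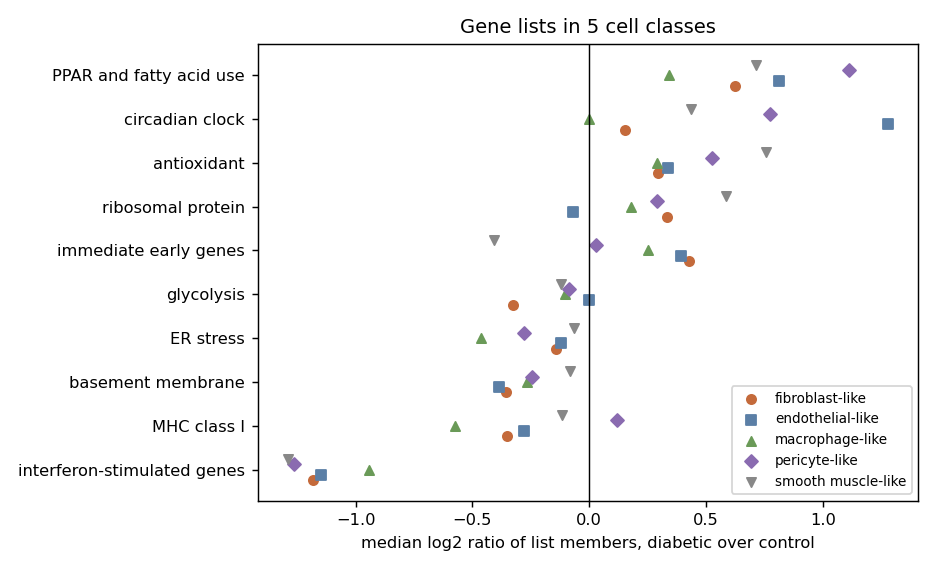
Median log2 ratio of diabetic over control CPM for 10 gene lists, with a point for each of the 5 compared cell classes. Interferon-stimulated genes ran from -1.29 to -0.94 and genes of PPAR signalling and fatty acid use from 0.34 to 1.11 across the 5 classes.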

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

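The look at Postn by cluster and in cells left out as doublets, and at the classes above the mitochondrial maximum, was chosen after the results had been seen. Differences between cell classes given here were not tested.

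Some genes stood higher in the diabetic library in 1 class and lower in another. Heart muscle transcripts, which are foreign to all 4 classes except where smooth muscle shares some of them, had a median log2 ratio of 0.70 in pericyte-like cells, though 0.11 as a mean over cells and -0.037 at resolution 0.5. The median was -1.26 in fibroblast-like, -1.51 in macrophage-like and -0.73 in smooth muscle-like cells. In the last class the list moved both ways, with Tnnt2 at 1.51 and Actc1 at 1.63, its median was -0.17 as a mean over cells, and its summed level was 1383 CPM in diabetic and 1349 CPM in control cells. Cxcl10, an interferon-induced chemokine, had a log2 ratio of 0.78 in macrophage-like cells (0.65 to 0.90), -0.83 in endothelial-like cells (-0.94 to -0.73) and -3.27 in pericyte-like cells (-5.59 to -1.65, from 3 diabetic and 59 control UMIs). Postn had a log2 ratio of 2.95 in smooth muscle-like and -1.57 in fibroblast-like cells. In smooth muscle cluster 13 Postn stood at 27.0 CPM in control and 28.9 CPM in diabetic cells (20 UMIs each), while the diabetic cells of cluster 24 had 581 CPM (192 UMIs), so the smooth muscle difference lay in cluster 24. With no doublets left out, Postn in smooth muscle-like cells stood at 0.861 of its control level (0.718 to 1.03), as the 16 control cells left out as doublets held 222 Postn UMIs. Their median depth was 14284 UMIs against 8656 in the kept control cells, so true doublets among them are not excluded.

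Other signals lay in cells that no expression comparison used. Barcodes with at least 300 genes and above 25% mitochondrial UMIs were 25.7% of the diabetic and 12.1% of the control library. When they were clustered with the rest, 41.4% of the diabetic ones (887 cells) and 10.9% of the control ones (109 cells) were endothelial-like, while 50.4% and 69.7% stayed unnamed. Cardiomyocyte-like cells, whose cluster was led by the atrial muscle hormone Nppa, were 1.44% of retained diabetic cells and 0.752% of control cells. These shares were 6.50% and 8.77% with classes named per cell, which turned the direction, and 0.877% and 0.174% at resolution 0.5. Neutrophil-like cells were 0.493% (27 cells) and 0.0579% (4 cells).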

How the results depend on the processing

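Alternatives on the unnamed cluster led by Wif1 and Comp, on leaving out the Lox-highest sub-cluster or smooth muscle cluster 24, on counting unnamed cluster 16 as macrophage-like, on leaving out the sub-cluster led by endothelial genes, on giving unnamed clusters their best class and on naming without the leading-gene rule were chosen after seeing the data, as were the sub-clusters without differing genes. A list median had a direction outside the middle 95% of its matched random lists, and a gene ratio where its interval excluded 0. Over all alternatives, 1183 of 1203 values of such medians and 2966 of 2981 of such gene ratios kept their sign. The few named genes that are not used here were left out of these tallies. Of 866 values of medians with no direction, 188 took the other sign. Of the fibroblast-like, endothelial-like and macrophage-like share ratios, Lox values and counts of list members, 170 were labelled unchanged, 22 moved and 2 reversed. Of the other values 4081 were labelled unchanged, 1242 moved and 36 reversed. Unchanged meant within the interval for values that carry one. Counts of list members carry no interval, so for these the label rested on closeness to the main value only. Alternatives compared expression in classes with at least 20 cells per library. With at most 10% mitochondrial UMIs pericyte-like values rested on 53 diabetic cells, and smooth muscle-like cells were too few. Depth limited the pericyte-like and smooth muscle-like classes most, with 2745 and 2736 genes at 100 UMIs or more against 9962 in fibroblast-like cells.

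The fibroblast-like share ratio was 2.45 with at most 10% mitochondrial UMIs, 0.835 with no maximum, 1.48 with Scrublet's own threshold, 1.19 with no doublets left out and 1.3 with no maximum and no leading-gene rule. The endothelial-like ratio was 0.378 with at most 10%, 0.867 with at least 1000 UMIs, 1.10 at resolution 2, 0.884 with unnamed clusters given their best class and 1.11 with no maximum and no leading-gene rule. The macrophage-like ratio was 1.21 with at most 10% and 0.738 at resolution 2. The cardiomyocyte-like ratio was 0.742 with classes named per cell. Without the leading-gene rule the fibroblast-like ratio was 1.62 with Scrublet's own threshold and 1.58 with no doublets left out, within its interval, so that rule's choice of clusters made the difference there. With no maximum the rule made part of it, and the cause was not tested for the others. The log2 ratio of Lox was 0.85 with no maximum, 1.31 with Scrublet's own threshold, 1.34 with no doublets left out and 1.26 without the Lox-highest sub-cluster. Without the leading-gene rule it stayed within its interval under the first 3, so that rule's choice of clusters made the difference. The percent of diabetic fibroblast-like cells with a Lox UMI, thinned, was 4.17, 6.60, 8.44 and 6.92 under these 4 settings. Thinned to 2000 UMIs the Lox shares were 5.68% of control and 18.1% of diabetic cells, and 21.1% and 38.7% without thinning, as greater depth shows more UMIs.

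The medians and genes that had a direction and reversed follow, and except for Fmo2 and Postn the cause was not tested. In fibroblast-like cells contractile genes had -0.084 as a mean over cells. TGF-beta genes had -0.022 and insulin and FoxO genes -0.11 with no maximum, and -0.063 and -0.055 with Scrublet's own threshold, and Cnmd had -1.02 with no maximum. Fmod had 0.088 and Actn1 0.24 with no maximum, and 0.20 and 0.0096 with no doublets left out. The median log2 ratio of chemokines and cytokines, endothelial-like, was 0.18 with at most 10%, 0.088 at resolution 0.5, 0.39 with classes named per cell and 0.21 with 1 UMI added. In the same cells respiratory chain genes had -0.013 with CPM over all genes. Heart muscle transcripts had 0.14, cell cycle genes 0.48 and Top2a 0.51 with at most 10%. Lipid-associated macrophage genes had -0.0079 and Plac8 2.58 with classes named per cell. In pericyte-like cells heart muscle transcripts had -0.037 at resolution 0.5 and Nppa -0.26 with at most 10%, and Acta2 had 0.284 with Scrublet's own threshold and 0.276 with no doublets left out. In smooth muscle-like cells hypoxia targets had -0.22 with classes named per cell, -0.045 with 1 UMI added and -0.25 without cluster 24. Mitochondrially encoded genes had 0.34 with classes named per cell. Fmo2 had -0.14 and Postn -0.22 both with Scrublet's own threshold and with no doublets left out, the latter returning 16 control cells that held 487 Fmo2 and 222 Postn UMIs. Without cluster 24 TGF-beta genes had -0.21, mitochondrially encoded genes 0.080 and Fmo2 -0.71.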

Other observations

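Of the tests below, those of Tbx5 and within sub-clusters, and the profile of the Lox-highest sub-cluster, were chosen only after the results had been seen.

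The Lox-highest fibroblast sub-cluster was higher than the other diabetic fibroblast-like cells in Hp, Saa3 and Lcn2 and lower in fibrillar collagens. Hp (haptoglobin) was 40.6-fold higher (27.4 to 62.4), Saa3 (serum amyloid A) 32.3-fold (22.5 to 47.7), Lcn2 (lipocalin 2) 21.9-fold (16.9 to 28.6), Apod, a lipid carrier, 9.0-fold (8.35 to 9.71), Serpina3n 5.06-fold (4.71 to 5.44) and C4b 3.59-fold (3.32 to 3.88). These genes helped to define the sub-cluster, so their height in it is a description. Its Lox level was 4.45-fold that of the other diabetic cells (4.0 to 4.95), while Col3a1 stood at 0.0998 of theirs (0.0887 to 0.112), Col1a1 at 0.233 (0.209 to 0.260) and Postn at 0.127 (0.0888 to 0.177). Of 6 measured fibrillar collagens 6 were at least 1.5-fold lower there, with a median log2 ratio of -1.13, and other interstitial collagens had -1.27. Complement genes had a median of 0.40 with 5 of 11 higher, and chemokines and cytokines 0.15 with 4 of 14 higher and 1 lower.

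Nr1d1 was higher in each of the 5 compared classes, with log2 ratios from 1.42 to 6.16 and no interval reaching 0. Dbp (0.04 to 3.6), Nr1d2 (0.29 to 1.63) and Per1 (0.19 to 0.27) had ratios above 0 in 5 of 5 classes. The interval included 0 for Dbp in macrophage-like cells, for Nr1d2 in smooth muscle-like cells and for Per1 in macrophage-like, pericyte-like and smooth muscle-like cells. Clock had ratios below 0 in 5 of 5 classes, from -1.17 to -0.17, with an interval that included 0 in macrophage-like cells (-0.57 to 0.21). Other clock genes went both ways between classes. Per2, Per3 and Tef were above 0 in 3 classes and below 0 in 2, and Bhlhe40 above in 1 and below in 4. In the classes where they had a ratio, Arntl was above 0 in 1 and below in 2, and Ciart above in 2 and below in 1. Bhlhe41 and Hlf were above 0 in 4 of 4. The hour of collection was not given for either library, so these clock values cannot separate diabetes from the hour.

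The first pattern weighed is fibroblast sub-cluster 5, the highest in Lox, which held no control cells, and its median depth of 0.847 that of the other diabetic fibroblast-like cells (0.807 to 0.884) argues against doublets. A shift of all fibroblast-like cells may account for part of the Lox difference, since Lox was 2.40-fold higher outside the sub-cluster (2.11 to 2.74). In 1 of 4 sub-clusters, however, the interval of its log2 ratio included 0. The pooled 2.40-fold can also hold other Lox-high groups made mostly of diabetic cells. At resolution 0.8 a further sub-cluster, of 70 diabetic and 2 control cells, had 250 CPM (139 Lox UMIs). Cells from a part of the tissue present in 1 preparation only cannot be told apart, because 6 heart transcription factors went both ways around a median ratio of 0.999 (0.841 to 1.10), Tcf21 at 1.71 (1.6 to 1.82) and Tbx20 at 0.573 (0.501 to 0.654). Nor can another heart region sampled in 1 preparation, because Tbx5 had 0 UMIs in the sub-cluster and 14 elsewhere, a ratio of 0 (0 to 1.36). Diabetes itself, or any other difference between the 2 preparations, stays open and untested.

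The next is the lower level of interferon-stimulated genes in diabetic endothelial-like cells. A few strongly exposed cells do not account for it, since the median log2 ratio was -1.10 (-1.15 to -1.06) without the interferon-led cluster. Cells with high mitochondrial percentages, or the mitochondrial maximum, do not either, since it was -0.99 (-1.09 to -0.90) among cells with at most 10% mitochondrial UMIs. Damage that mitochondrial UMIs do not show was not tested. The difference is consistent with exposure of the whole control tissue, since fibroblast-like and macrophage-like cells shared it, the median nearer 0 being -0.94 (-1.09 to -0.88). Whether it belongs to diabetes, to the control animals or to the handling of 1 preparation stays untested.

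The last is the 18.9-fold higher Cyp1a1 in diabetic endothelial-like cells. Its level in diabetic fibroblast-like cells was 0.0125 of that in endothelial-like cells (0.00876 to 0.0173), which argues against free RNA shared by all classes. Haemoglobin RNA, however, was 4272 CPM in diabetic endothelial-like and 19.3 CPM in diabetic fibroblast-like cells. Foreign RNA can thus be uneven between these classes, so free RNA confined to endothelial-like cells is not excluded. Exposure to an aryl hydrocarbon receptor ligand, the hour of collection, and diabetes itself may each contribute and were not tested.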
